A study of Drosophila melanogaster with 24 samples.

How the data were processed

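Ovaries of tra2ts and w1118 females and testes of TraF and Control males were profiled by RNA-seq after 0, 12 and 24 h at the restrictive temperature, 29 °C for ovaries and 30 °C for testes per the extraction notes in the labels; the treatment text of the labels gives 29 °C for all. Per the labels, late egg chambers were discarded at dissection. Per the submitters' processing notes, the authors aligned single-end reads with TopHat 1.4.1 to the genome build dm3 and counted reads per gene with HTSeq. The deposited files hold raw read counts per gene, with no normalization, in 1 file per library. The HTSeq version, the annotation release and the strand setting were not given in the sources used here. Each file has 15406 genes and 5 summary lines, which were left out of library sizes and tests. Symbols were found for 14732 of the 15406 gene identifiers, and the rest keep their identifier. Chromosome arms, exonic lengths and exon overlaps came from a later annotation of the same species, matched by identifier, so no coordinates are given.

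The total gene count per library ran from 16136939 to 32782474, and reads outside genes were 1.07% to 2.48% of reads. Intervals of count ratios and bounds cover counting error only, since counts were pooled over the libraries of a group. Reads carry no molecular identifiers, so duplicate reads could not be told apart.

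Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. For each tissue, 1 model with a mean per group was fitted to its 12 libraries, so that groups of 2 share an estimate of the spread. Genes were filtered with filterByExpr by group, which left 8784 in ovaries and 12083 in testes, and 12411 for ovary against testis over all 24 libraries. Libraries were scaled by TMM and tested with edgeR's two-sided quasi-likelihood test (glmQLFit, glmQLFTest). Adjusted p are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes used edgeR's prior count of 0.125. Where the lower group had 0 counts, the fold is a lower bound with 3 counts over the group, and where it had 1 to 3 counts, the ratio of pooled counts is given with its exact 95% interval.

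The comparisons were the genotypes at each time, 12 h and 24 h against 0 h in control genotypes, the switch (the genotype difference in change from 0 h) and control ovary against control testis at 0 h. The 2 switch comparisons per tissue were the main ones. The time courses of tra2ts and TraF, the comparisons of sign and overlap between time courses, and the runs without libraries that stood apart were added after the data were seen. Fisher's exact test was planned for calls shared between the switches of both tissues, and with 0 ovary calls it was void; correlations between tissues are across genes.

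The 25 gene lists were fixed before the data were examined: heat shock, sex determination, DSX targets with yolk proteins, dosage compensation, eggshell, female germline, female soma, testis soma, meiotic arrest, spermatid, Y-linked, JAK/STAT, ecdysone, circadian, antimicrobial, accessory gland, fat body, muscle, hemocyte, reproductive tract, gut, transgene markers, ribosomal protein, proteasome and detoxification. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 323 tests, 77 passed, and 2 of these also passed with the correlation estimated from the data. They were DSX targets in the ovary switch at 12 h and gut in the testis genotype comparison at 0 h. Each list call was repeated without each library of the compared groups, chosen after the data were seen. Sex-biased lists, at least 4-fold apart between control ovaries and testes, were tested in the genotype comparisons at 12 h and 24 h, which share no library with their definition. Where a list held genes at 0 in a group, the medians were also taken with these at their bound.

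Named genes followed a rule set before the data were examined. For a switch comparison it takes called genes with a mean of at least 1 CPM in a compared group: the 8 largest rises and 8 largest falls, then 5 more each with a symbol other than CG or CR, or the 5 with the lowest p where fewer than 5 pass. Other comparisons take the 5 largest rises and 5 largest falls. Always named are tra, tra2, dsx, fru, Sxl, Yp1, Yp2, Yp3, w and up to 4 members of each called list. Cyp4g1 and w levels, Fad2 in testes, the overlap partner l(3)73Ah, Arc1, and genes named from the alternatives and from the added time courses were chosen after their values were seen.

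Alternatives set before the data were examined were RLE scaling, no filter on low counts, DESeq2, a replicate block, a robust prior, fits of the compared groups alone, and leaving out each library of the compared groups in turn. For a group left with 1 library, the fit assumes that it varies like the others. The pipeline was tested on counts simulated around each gene's mean over the libraries of a tissue. In these, 50 genes each were changed 2-, 4-, 8- and 16-fold in the tra2ts or TraF 24 h group alone. In the ovary switch 2%, 46%, 70% and 86% were recovered, and in the testis switch 12%, 68%, 88% and 92%, with 8 and 7 unchanged genes called. Splits of the samples were not counted, since groups hold 2 libraries, and outlier tests need larger groups.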

Results

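The series holds 24 RNA-seq libraries from Drosophila melanogaster gonads, in 12 groups of 2 independent dissections. In 12 ovary libraries, XX females carrying temperature-sensitive alleles of the splicing factor tra2 (tra2ts) were set beside w1118 females. In 12 testis libraries, XY males carrying a heat-inducible female form of tra (TraF) were set beside males with the driver and repressor alone (Control). All flies were raised at 18 °C and shifted at 5 days of age, and gonads were taken after 0, 12 and 24 h. Per the labels, the shift moves tra2ts ovaries from the female to the male isoform of the sex determination protein DSX, and TraF testes from the male to the female isoform. The total gene count per library ran from 16136939 to 32782474. Levels are CPM, counts scaled to library size by edgeR, as the mean ± SD of n = 2 libraries per group, and log2 fold changes carry the standard error (SE) of the fit. A gene is called where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p under 0.05. Each switch comparison is the change from 0 h in the experimental genotype minus its control's. It cannot tell the isoform switch from stock-specific responses to temperature. Of the 77 gene list calls by camera in the planned comparisons, 56 were lost or turned in direction without at least 1 library of the compared groups, and those libraries, each left out alone, are named with the adjusted p without them.

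The gene that the testis transgene encodes, tra (FBgn0003741, arm 3L), rose in TraF testes after the shift. It stood at 21.4 ± 2.12 CPM at 0 h, 229 ± 18.1 CPM at 12 h and 262 ± 33.7 CPM at 24 h, against 10.2 ± 0.894, 6.52 ± 1.29 and 5.91 ± 0.746 CPM in Control testes. In the switch comparison its log2 fold change was 4.07 (SE 0.258, adjusted p = 9.66e-05 by edgeR) at 12 h and 4.41 (SE 0.26, adjusted p = 4.52e-05) at 24 h. It was already higher in TraF than in Control testes at 0 h, with a log2 fold change of 1.07 (SE 0.178, adjusted p = 0.016 by edgeR). Counts do not tell transgene reads from those of the endogenous gene. The exons of tra overlap those of l(3)73Ah on the other strand, which stood between 47 and 55.6 CPM in all 6 testis groups.

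**Figure D1:**
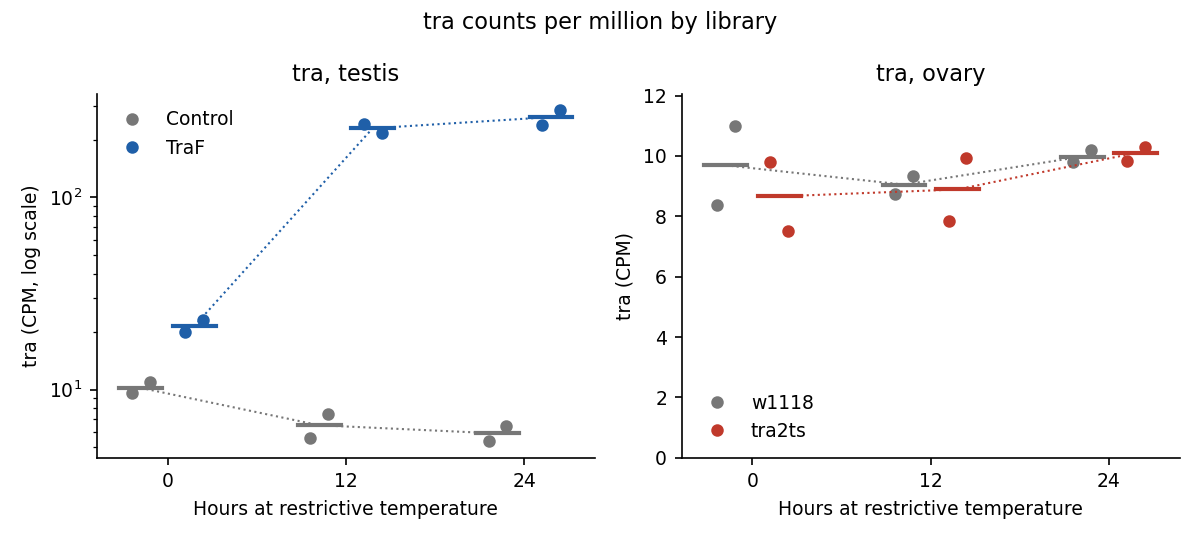
CPM of tra in testes (left, log scale) and ovaries (right, linear scale) against hours at the restrictive temperature. Points are libraries, short bars are means of 2 libraries and dotted lines join the means of a genotype. TraF testes reached 229 CPM at 12 h and 262 CPM at 24 h, and ovaries of both genotypes had means between 8.66 and 10.1 CPM.

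No other gene was called in the testis switch comparison, so tra was the 1 called gene of 12083 tested at each time. At an unadjusted p under 0.05 there were 259 genes at 12 h and 376 at 24 h, and DESeq2 called 4 and 3 genes. Besides tra, the genes that DESeq2 called were lncRNA:CR43414 at both times, yip7 at both times and Cyp6a14, a cytochrome P450, at 12 h. lncRNA:CR43414 stood at 2.81 ± 0.391, 8.62 ± 1.63 and 12.3 ± 0.153 CPM in TraF testes at 0, 12 and 24 h, against 39.9 ± 0.713, 45.8 ± 2.61 and 53.6 ± 9.59 CPM in Control testes. Its log2 fold change in the switch comparison at 24 h was 1.70, with an adjusted p of 0.269 by edgeR. Cyp6a14 stood at 1.07 ± 0.0568, 12.1 ± 0.518 and 3.10 ± 0.366 CPM in TraF testes, and its log2 fold change at 12 h was 2.53 (adjusted p = 1 by edgeR). The next genes by p did not pass either: SP1173 (-1.71) and Obp56c (2.18) at 12 h, and ple, which encodes tyrosine hydroxylase (-1.35), Mmp2, a matrix metalloproteinase (-1.34), and Ir7c (2.61) at 24 h. Leaving out Control 12 h replicate 2 gave 96 genes at 12 h. Its partner, Control 12 h replicate 1, held far more accessory gland transcripts, with Acp36DE at 1320 against 8.9 CPM.

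The sex determination genes dsx, fru, Sxl and tra2 were not called in the testis switch comparison. dsx, which encodes both DSX isoforms, stood at 6.09 ± 0.341, 8.86 ± 0.841 and 10.9 ± 6.89 CPM in TraF testes and 5.18 ± 1.07, 5.53 ± 0.282 and 7.29 ± 2.01 CPM in Control testes. Counts per gene do not separate the isoforms. Among 15 tested members of the sex determination list, tra alone rose, both over all genes and adjusted over the list alone. The list had a camera adjusted p of 0.0416 at 12 h and 0.000294 at 24 h (adjusted p = 0.488 and 0.199 with an estimated correlation). At 12 h its median, -0.09, and its mean, 0.05, differed in sign. Without TraF 0 h replicate 2, TraF 12 h replicate 2, Control 0 h replicate 1, Control 12 h replicate 1 or Control 12 h replicate 2 the adjusted p was 0.0585 to 0.487.

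Marker lists of gonadal somatic cells had medians below 0 in the testis switch comparison, with 0 members called over all genes or adjusted over the list alone by edgeR. The female soma list (19 tested) had a median log2 fold change of -0.25 at 12 h and -0.20 at 24 h, with camera adjusted p of 0.00451 and 0.000972 (adjusted p = 0.657 and 0.586 with an estimated correlation). Its adjusted p at 12 h was 0.058 without TraF 0 h replicate 1, 0.0667 without TraF 12 h replicate 2, 0.187 without Control 0 h replicate 1 and 0.547 without Control 12 h replicate 2. For 24 h it was 0.183 without Control 24 h replicate 1. Its members aop, ptc, which encodes the Hedgehog receptor, and kek1 had log2 fold changes of -0.97 (SE 0.34), -1.21 (SE 0.421) and -0.82 (SE 0.288) at 24 h. The testis soma list (22 tested), which shares tj, eya, Fas3, hh, Wnt2 and ptc with it, had a median of -0.22 at 12 h (camera adjusted p = 0.00451, adjusted p = 0.488 with an estimated correlation). The call was lost without TraF 12 h replicate 1 (adjusted p = 0.107), Control 0 h replicate 1 (0.107) and Control 12 h replicate 2 (0.547). The spermatid list (49 tested) had a median of 0.24 at 12 h (camera adjusted p = 0.000369, adjusted p = 0.69 with an estimated correlation). It did not pass without TraF 0 h replicate 1 (adjusted p = 0.798) or Control 0 h replicate 2 (0.427). These 3 lists at 12 h were also tested without the Control library with accessory gland transcripts, which gave medians of -0.39, -0.38 and 0.14 and adjusted p of 0.00109, 0.00101 and 0.0495.

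The gut list (9 tested) had a median of 1.36 at 12 h and 1.04 at 24 h in the testis switch comparison, with camera adjusted p of 6.99e-06 and 0.000128 (adjusted p = 0.143 and 0.183 with an estimated correlation) and 0 members called by edgeR over all genes or adjusted over the list alone. Its member Amy-p, an amylase, had log2 fold changes of 0.98 (SE 0.398) and 1.30 (SE 0.395). The 0 h libraries enter these values, and Control 0 h replicate 1 stood apart, with a list median of 1.31 log2 CPM against -0.985 in its partner and at most 0.0625 in the other testis libraries. Without it the medians were 0.73 at 12 h (adjusted p = 0.00229) and 0.13 at 24 h (adjusted p = 0.00155).

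Clock, muscle and other lists also passed in the testis switch comparison, with 0 members called by edgeR over all genes or adjusted over each list alone, and each was lost without at least 1 library. The circadian list (15 tested) had a median of -0.20 at 12 h and -0.14 at 24 h, with camera adjusted p of 0.000364 and 0.0167 (adjusted p = 0.298 and 0.586 with an estimated correlation). Its adjusted p was 0.183 at 12 h without Control 12 h replicate 2, and at 24 h it was 0.212 without TraF 24 h replicate 1, 0.0995 without Control 24 h replicate 1 and 0.117 without TraF 0 h replicate 1. At 12 h, Pdp1, vri and tim, which belong to the clock's feedback loops, had log2 fold changes of -0.84 (SE 0.242), -1.96 (SE 0.635) and -0.91 (SE 0.389). vri stood at 8.42 ± 0.878 CPM in Control testes at 0 h and 30.4 ± 1.84 CPM at 12 h, against 9.80 ± 3.37 and 9.06 ± 3.66 CPM in TraF testes. The muscle list (20 tested) had medians of -0.28 and -0.30, with camera adjusted p of 0.00938 and 0.000294 (adjusted p = 0.69 and 0.586 with an estimated correlation). Its adjusted p at 12 h was 0.333 without TraF 0 h replicate 2, 0.0783 without TraF 12 h replicate 2, 0.0946 without Control 0 h replicate 2 and 0.185 without Control 12 h replicate 2. For 24 h it was 0.446 without TraF 24 h replicate 1 and 0.0791 without Control 24 h replicate 2. The hemocyte list (11 tested) had a median of -0.46 at 24 h (camera adjusted p = 0.0409, adjusted p = 0.586 with an estimated correlation). Leaving out TraF 0 h replicate 2, TraF 24 h replicate 1, Control 0 h replicate 2 or Control 24 h replicate 1 gave an adjusted p of 0.274 to 0.469. The detoxification list of glutathione S-transferases and cytochrome P450s (81 tested) had a median of -0.16 at 24 h (camera adjusted p = 0.0315, adjusted p = 0.833 with an estimated correlation). Without TraF 0 h replicate 1, TraF 24 h replicate 2, Control 0 h replicate 2, Control 24 h replicate 1 or Control 24 h replicate 2 the adjusted p was 0.0617 to 0.645. The accessory gland list (15 tested) had a median of -7.96 at 12 h (camera adjusted p = 1.74e-08, adjusted p = 0.488 with an estimated correlation), and without Control 12 h replicate 1, which held those transcripts, the median was 0.50 and the adjusted p 0.252. Without that library the circadian median at 12 h was -0.38 (adjusted p = 0.000964), the muscle median at 12 h -0.16 (adjusted p = 0.0495), and the hemocyte adjusted p at 24 h 0.0563.

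In the ovary switch comparison at 12 h, yolk protein genes and other genes described as DSX targets lay lower as a group. Their change from 0 h was lower in tra2ts than in w1118 ovaries. Whether DSX acts on them in ovaries was not tested. Of 8 tested members of this yolk protein and DSX target list, 1 was above 0, and the median log2 fold change was -0.75. The camera adjusted p was 9.66e-07 (adjusted p = 0.0395 with an estimated correlation, and 0.0857 with an estimated correlation and a replicate block). The call with an estimated correlation was lost without each of the 8 libraries in turn, with adjusted p of 0.0539 (without tra2ts 0 h replicate 1) to 0.213 (without tra2ts 12 h replicate 1), and at the preset correlation it passed without each. That call was also lost without the member Fad2 (adjusted p = 0.454), bab2 (0.154), Yp1 (0.0745), Yp2 (0.0685) or bond (0.054), each left out alone. Yp1 (FBgn0004045) and Yp2 (FBgn0005391), which encode yolk proteins, had log2 fold changes of -1.05 (SE 0.456) and -1.04 (SE 0.488). Yp1 stood at 7400 ± 2170 and 8100 ± 2220 CPM in tra2ts ovaries at 0 and 12 h, and at 3410 ± 476 and 7710 ± 700 CPM in w1118 ovaries. Yp2 stood at 10000 ± 3250 and 10100 ± 3350 CPM in tra2ts ovaries, and at 3960 ± 48.8 and 8240 ± 1330 CPM in w1118 ovaries. At 12 h itself tra2ts ovaries did not lie below w1118 ovaries in either gene, with log2 fold changes of 0.07 (SE 0.322) for Yp1 and 0.30 (SE 0.344) for Yp2, against 1.12 (SE 0.326) and 1.34 (SE 0.35) at 0 h. From 0 to 12 h, Yp1 and Yp2 had log2 fold changes of 1.18 (SE 0.326) and 1.06 (SE 0.348) in w1118 and 0.13 (SE 0.322) and 0.02 (SE 0.344) in tra2ts ovaries. The other members were Yp3 (-0.43), bond (-0.76), bab2 (-0.75), Desat1 (-0.17), bab1 (0.91) and Fad2 in the switch comparison. Exons of Yp1 overlap an antisense RNA gene on the other strand.

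Fad2 (FBgn0029172), a desaturase of female pheromone synthesis, had the lowest p of the list. It had 124 counts in tra2ts ovaries at 0 h, 1 at 12 h and 2 at 24 h, against 131 and 115 counts in w1118 ovaries at 12 and 24 h. The ratio of w1118 to tra2ts was 133 (95% counting interval 23.5 to 5300) at 12 h and 57 (15.4 to 476) at 24 h. Libraries of the same group also differed, with 41 and 90 counts in w1118 ovaries at 12 h and 98 and 17 at 24 h. By edgeR its adjusted p in the switch comparison was 1, and 0.0518 at 12 h when adjusted over the list alone. No member passed either way. At 24 h the list's median was -0.43 (camera adjusted p = 0.0117, adjusted p = 0.571 with an estimated correlation). Its adjusted p was 0.0583 to 0.238 without tra2ts 0 h replicate 2, tra2ts 24 h replicate 1, tra2ts 24 h replicate 2, w1118 0 h replicate 1, w1118 0 h replicate 2 or w1118 24 h replicate 2, and its unadjusted camera p was 0.0845 without Fad2. Without the 2 ovary 24 h libraries with the most reads outside genes the median was -0.65 (adjusted p = 0.0297).

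**Figure D2:**
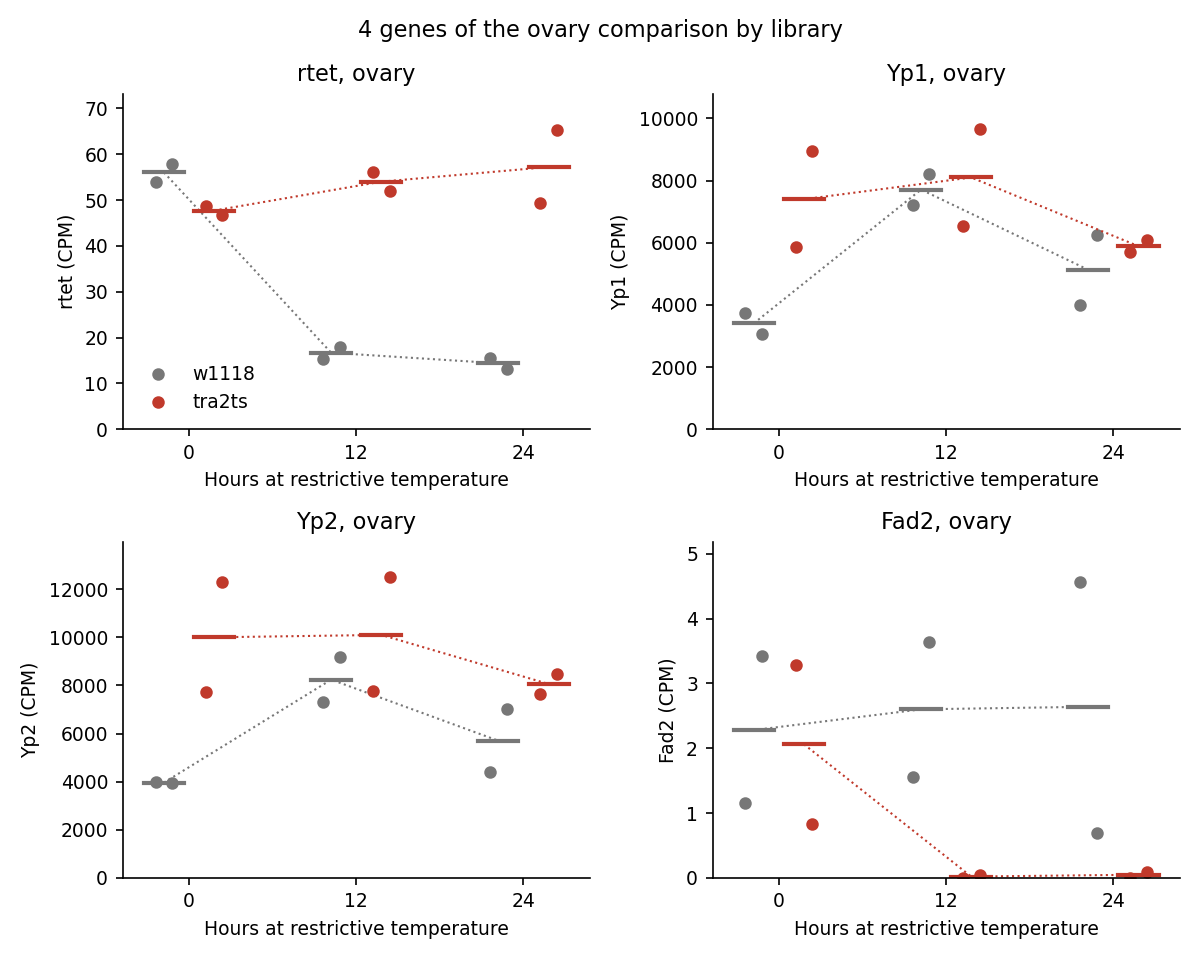
CPM of rtet, Yp1, Yp2 and Fad2 in ovaries against hours at the restrictive temperature. Points are libraries, short bars are means of 2 libraries and dotted lines join the means of a genotype. rtet went from 56.0 to 14.4 CPM in w1118 ovaries and from 47.7 to 57.2 CPM in tra2ts ovaries, and Fad2 was at 2 counts or fewer in tra2ts ovaries at 12 and 24 h.

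No gene was called in the ovary switch comparison by edgeR, with 0 of 8784 tested at each time. At an unadjusted p under 0.05 there were 58 genes at 12 h and 117 at 24 h, and DESeq2 called 1 gene at each time, rtet (FBgn0028468, arm 3R). rtet stood at 47.7 ± 1.28, 54.0 ± 2.82 and 57.2 ± 11.2 CPM in tra2ts ovaries at 0, 12 and 24 h, against 56.0 ± 2.74, 16.7 ± 1.75 and 14.4 ± 1.66 CPM in w1118 ovaries. Its log2 fold change was 1.92 (SE 0.269, adjusted p = 0.304 by edgeR) at 12 h and 2.22 (SE 0.27, adjusted p = 0.092) at 24 h. It also passed at 24 h without tra2ts 24 h replicate 1, with an adjusted p of 0.0255 by edgeR. Other genes with a low p did not pass (adjusted p = 1 by edgeR): sif (5.78), lncRNA:CR43651 (2.89), FBgn0040994 (2.53) and CG42489 (-2.95) at 12 h, and FBgn0040994 (2.53), Cyp4d8 (2.48), PGRP-LC, which encodes a peptidoglycan sensor (2.12), and CG1572 (1.63) at 24 h. The w1118 ovaries held 0 counts of sif at 12 h, so its 5.78 depends on edgeR's prior count. Counts were also simulated around each gene's mean over the ovary libraries, with changes put in the tra2ts 24 h group alone. There, 46% of genes changed 4-fold and 70% of genes changed 8-fold were recovered. The simulation held no libraries that stood apart, so these shares need not hold for the real libraries.

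Other lists that passed in the ovary switch comparison were each lost without at least 1 library, and edgeR called 0 of their members over all genes or adjusted over the list alone. At 12 h heat shock genes (18 tested) had a median of -0.45 (camera adjusted p = 9.66e-07, adjusted p = 0.593 with an estimated correlation). This list lost its call without tra2ts 0 h replicate 1 (adjusted p = 0.0805) and w1118 12 h replicate 1 (0.0504). Its member Hsp68 had a log2 fold change of -3.13 (SE 1.72). Proteasome genes (33 tested) had a median of -0.18 (camera adjusted p = 0.00261, adjusted p = 0.914 with an estimated correlation). No call remained without w1118 0 h replicate 2 (adjusted p = 0.585), w1118 12 h replicate 2 (0.295) or tra2ts 12 h replicate 1 (0.189). At 24 h, antimicrobial genes (21 tested) had a median of 2.51 (camera adjusted p = 1.5e-06, adjusted p = 0.784 with an estimated correlation), with TotM at 6.82 (SE 2.1). Without w1118 0 h replicate 2, whose list median of 1.47 log2 CPM stood against -2.29 in its partner, the antimicrobial median was -0.37 and the adjusted p 0.0825. Eggshell genes (27 tested) had a median of -0.45 (camera adjusted p = 0.000996, adjusted p = 0.784 with an estimated correlation), with Mur11Da at -3.19 (SE 1.45). Leaving out tra2ts 0 h replicate 1, tra2ts 24 h replicate 1, w1118 0 h replicate 2 or w1118 24 h replicate 2 gave an adjusted p of 0.0583 to 0.942. The detoxification list (64 tested) had a median of 0.27 (camera adjusted p = 0.00128, adjusted p = 0.784 with an estimated correlation). The call was lost without w1118 0 h replicate 2 (adjusted p = 0.124), tra2ts 24 h replicate 2 (0.836) and w1118 24 h replicate 2 (0.734). Ribosomal protein genes (82 tested) had a median of 0.30 (camera adjusted p = 2.87e-05, adjusted p = 0.961 with an estimated correlation). Without tra2ts 0 h replicate 1, tra2ts 24 h replicate 2, w1118 0 h replicate 2 or w1118 24 h replicate 2 the adjusted p was 0.0859 to 0.937. The 24 h groups hold a library of each genotype with 2.47% and 2.48% of reads outside genes, against at most 1.58% in the other 10 ovary libraries. Without those 2 libraries the 24 h adjusted p were 0.0301 (antimicrobial, median 1.60), 0.0041 (eggshell, median -0.74), 0.0297 (detoxification, median 0.12) and 0.804 (ribosomal protein).

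The switches were compared between tissues over 8485 genes tested in both. With 0 genes called in the ovary switch at 12 h and at 24 h, shared calls could not be tested. Across genes, which are not independent replicates, the ovary and testis log2 fold changes had Pearson's r of -0.014 and Spearman's rho of 0.057 at 12 h, and 0.15 and 0.18 at 24 h.

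**Figure D3:**
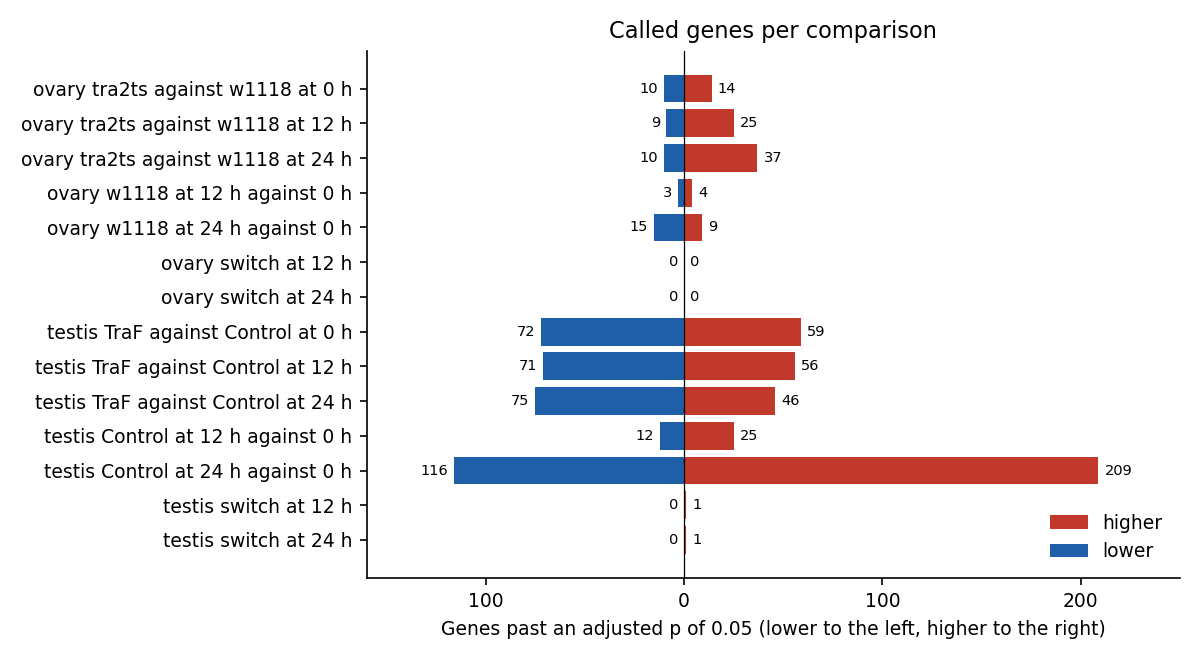
Called genes per comparison, those higher to the right and those lower to the left, at an adjusted p of 0.05 by edgeR. The switch comparisons held 0 genes in the ovary and 1 gene, tra, in the testis at each time, and the testis Control at 24 h against 0 h held 209 higher and 116 lower.

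Ovaries of tra2ts and w1118 females differed in single genes at 0 h and after the shift, bw and GstE1 among them. The eye pigment transporter gene bw (FBgn0000241) stood at 30.1 ± 3.78 CPM in tra2ts and 0.133 ± 0.0726 CPM in w1118 ovaries at 0 h, with a log2 fold change of 7.79 (adjusted p = 0.00215 by edgeR). It was 7.54 at 12 h and 7.49 at 24 h. GstE1, a glutathione S-transferase, stood at 4.09 ± 3.1 CPM in tra2ts and 52.5 ± 22.4 CPM in w1118 ovaries at 0 h, with log2 fold changes of -3.66, -4.58 and -3.80 at 0, 12 and 24 h. edgeR called 14 genes higher and 10 lower in tra2ts ovaries at 0 h, 25 and 9 at 12 h, and 37 and 10 at 24 h. Of the 47 genes called at 24 h, 46 had the same sign at 0 h, and 16 genes were called at all 3 times, among them bw, GstE1, GstE10, Cyp12c1, Rpn12R, Arc1 and nolo. Exons of bw overlap mi, those of GstE1 and GstE10 overlap each other and those of aft overlap Ubc10, each on the other strand, and the strand of the libraries was not given, so these counts are uncertain.

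The largest increases in tra2ts ovaries were in genes near the detection limit of w1118 ovaries. At 0 h they were CG13532 (at least 35-fold), Rpn12R, a proteasome subunit paralog (ratio 99, 95% counting interval 17.4 to 3940), Cyp12c1 (57.6, 15.6 to 481) and CG32199 (38.4, 12.9 to 189). At 12 h they included Rpn12R (at least 70.5-fold), sif (at least 44.9-fold), CG13532 (51.5, 17.3 to 252) and Dscam4, a cell adhesion gene, at 13.0 against 0.139 CPM (6.51). At 24 h they included Rpn12R (at least 60.5-fold), CG13532 (at least 47.8-fold), Acsx4 (at least 16.5-fold) and CG3397 (122, 21.5 to 4860). Besides GstE1, the largest decreases were CG6426 (-4.46), nolo (-4.19), CG6106 (-2.52) and aft (-2.31) at 0 h. At 12 h they were CG6426 (-5.63), nolo (-3.35), aft (-2.94) and Obp99a (-2.61), and at 24 h CG14118 (-3.93), CG6426 (-3.73), nolo (-3.27) and CG32641 (-3.07). Bounds set the lower group at 3 counts over its 2 libraries, and intervals and bounds cover counting error only.

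By group, muscle genes, which mark the sheath around the ovarioles, had medians above 0 in tra2ts against w1118 ovaries at each time, also without each library in turn (0.73 to 1.69). Of 19 tested, 17, 19 and 16 were above 0 at 0, 12 and 24 h, with medians of 1.05, 1.10 and 1.31 and camera adjusted p of 6.21e-10, 6.9e-12 and 4.26e-11 (adjusted p = 0.458, 0.235 and 0.23 with an estimated correlation). edgeR called 0 over all genes, and 8, 0 and 11 when adjusted over the list alone. Mhc, the muscle myosin heavy chain, was at 1.26 (SE 0.368) at 0 h and the troponin gene TpnC73F at 1.77 (SE 0.426) at 24 h. Hemocyte genes (11 tested) had medians of 1.31, 1.27 and 1.10, with camera adjusted p of 7.09e-09, 2.59e-05 and 0.000344 (adjusted p = 0.117, 0.235 and 0.23 with an estimated correlation). The adjusted p at 24 h was 0.0517 without tra2ts 24 h replicate 1. The median at 0 h was 0.94 to 2.15 without each library, with an adjusted p of 0.0173 with an estimated correlation without w1118 0 h replicate 2. None passed over all genes by edgeR, and adjusted over the list alone 5, 2 and 3 were higher and 1 was lower at 24 h. NimC1, a phagocytosis receptor, was at 6.16 (SE 1.09) at 0 h and the peroxidasin gene Pxn at 2.50 (SE 0.469) at 24 h.

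The detoxification list (64 tested) had 4 members higher and 1 lower at 12 h, and 5 higher and 1 lower at 24 h. Adjusted over the list alone these were 6 and 1 at 12 h, and 11 and 3 at 24 h. Its medians were 0.12 and 0.44, with camera adjusted p of 0.00578 and 1.49e-06 (adjusted p = 0.794 and 0.378 with an estimated correlation), and at 24 h the adjusted p was 0.06 without tra2ts 24 h replicate 2 and 0.0603 without w1118 24 h replicate 2. Those higher in tra2ts ovaries at 24 h included GstE10 (4.42, SE 0.44), Cyp12a4 (4.08, SE 0.511) and Cyp12d1-p (3.83, SE 0.485), and GstE10 and Cyp12d1-p were already higher at 0 h (4.04 and 2.89). Eggshell genes (27 tested) had medians of -0.55 at 0 h and -0.47 at 24 h, with camera adjusted p of 0.021 and 4.7e-07 (adjusted p = 0.85 and 0.23 with an estimated correlation). At 0 h the median was 0.16 (adjusted p = 0.168) without w1118 0 h replicate 1 and -0.27 (adjusted p = 0.248) without tra2ts 0 h replicate 2. edgeR called 0 over all genes, and 0 and 7 when adjusted over the list alone, among them Cp38 (-2.14, SE 0.525) and Cp19 (-3.43, SE 0.925) at 24 h. Antimicrobial genes (21 tested) had medians of 0.82 at 12 h and 2.70 at 24 h, with camera adjusted p of 0.0215 and 2.43e-06 (adjusted p = 0.794 and 0.45 with an estimated correlation). Their adjusted p at 12 h was 0.0572 without tra2ts 12 h replicate 1 and 0.707 without w1118 12 h replicate 2. edgeR called 0 over all genes and 2 adjusted over the list alone at 24 h, with Def at 5.17 (SE 1.21). Without the 2 ovary 24 h libraries with the most reads outside genes the medians at 24 h were 0.54 (detoxification), -0.89 (eggshell) and 1.25 (antimicrobial), with adjusted p of 0.000322, 1.04e-05 and 0.022, and the antimicrobial adjusted p at 12 h was 0.0561.

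Smaller shifts had edgeR calls of 0 except where given. Ribosomal protein genes (82 tested) had medians of -0.25 at 0 h and -0.25 at 12 h, with camera adjusted p of 0.000112 and 0.000655 (adjusted p = 0.942 and 0.936 with an estimated correlation). Its adjusted p was 0.801 without w1118 0 h replicate 2 and 0.608 without tra2ts 0 h replicate 1 at 0 h, and 0.826 without tra2ts 12 h replicate 1 and 0.707 without w1118 12 h replicate 2 at 12 h. At 12 h the heat shock list (18 tested) had a median of -0.21 (camera adjusted p = 0.0357, adjusted p = 0.794 with an estimated correlation). It did not pass without tra2ts 12 h replicate 2 (adjusted p = 0.142), tra2ts 12 h replicate 1 (0.0509) or w1118 12 h replicate 1 (0.783). The proteasome list (33 tested) had a median of -0.23 and a mean of 0.05 (camera adjusted p = 0.0357, adjusted p = 0.936 with an estimated correlation), with Rpn12R higher. This list lost its call without w1118 12 h replicate 2 (adjusted p = 0.495) and tra2ts 12 h replicate 1 (0.353). Genes higher in control testes than in control ovaries at 0 h, by at least 4-fold, had medians of 0.16 at 12 h and 0.15 at 24 h over 1418 genes. Their camera adjusted p were 0.000365 and 1.14e-05 (adjusted p = 0.327 and 0.23 with an estimated correlation), and 13 and 15 were called higher and 2 and 1 lower. With genes absent from a group at their bound the medians were 0.16 and 0.15, and the adjusted p at 12 h was 0.0938 without w1118 12 h replicate 2. Genes higher in control ovaries (1747 tested) had medians of -0.09 and -0.03, with camera adjusted p of 0.00593 and 0.0468 (adjusted p = 0.235 and 0.338 with an estimated correlation), and 4 and 7 were called higher and 1 and 2 lower. Their adjusted p at 12 h was 0.177 without w1118 12 h replicate 2 and 0.069 without tra2ts 12 h replicate 1. For 24 h it was 0.207 without tra2ts 24 h replicate 1, 0.122 without w1118 24 h replicate 1 and 0.0517 without the 2 libraries with the most reads outside genes. Both lists were chosen on the 0 h control libraries of this series, which are not among those compared here, and are not an outside source of evidence. At 0 h, where the w1118 libraries also defined the lists, the genotype medians were 0.17 (higher in testes) and -0.02 (higher in ovaries). In the switch comparison, which holds those libraries too, they were 0.03 and -0.03 at 12 h, and 0.06 and -0.007 at 24 h. The medians at 12 h and 24 h therefore do not show a change that followed the shift.

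Counts of called genes in the ovary genotype comparison depended on single libraries. Without tra2ts replicate 1, tra2ts replicate 2, w1118 replicate 1 or w1118 replicate 2 of the time in question, edgeR called 2, 2, 1 and 4 genes at 0 h, 1, 1, 6 and 4 at 12 h, and 72, 27, 16 and 4 at 24 h. It called 12 at 24 h without the 2 libraries with the most reads outside genes.

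Testes of TraF and Control males differed at 0 h and after the shift, in genes that lay mainly on chromosomes X and 2. lncRNA:CR43263 and the chorion gene Cp7Fb were lower in TraF testes at each time, and Cp7Fb stood at 0.023 ± 0.0326 against 11.5 ± 10.2 CPM at 0 h. CG34205 was higher at each time, with log2 fold changes of 4.55, 3.80 and 3.49 at 0, 12 and 24 h. Hsp70Bb stood at 1.43 ± 0.653, 10.7 ± 0.841 and 12.1 ± 0.0804 CPM in TraF testes and 0.511 ± 0.222, 0.972 ± 0.836 and 0.552 ± 0.178 CPM in Control testes. It passed at 12 h (3.45, adjusted p = 0.00632 by edgeR) and at 24 h (4.48, adjusted p = 0.00241). edgeR called 59 genes higher and 72 lower in TraF testes at 0 h, 56 and 71 at 12 h, and 46 and 75 at 24 h. Of the 120 genes other than tra called at 24 h, 117 had the same sign at 0 h, and 27 higher and 46 lower genes other than tra were called at all 3 times. Of the genes called at 24 h with a known arm, 107 of 115 (93%) lay on X or chromosome 2, against 55.2% of tested genes (odds ratio 11, 95% interval 5.4 to 26.2, two-sided Fisher's exact test p = 2.03e-19). Chromosome 2 held 75.7% of the called against 39.2% of the tested genes and X 17.4% against 15.9%, so that X alone had an odds ratio of 1.11 (0.648 to 1.82) against all other arms. Against chromosome 3 alone and without tra, a test chosen after the data were seen, the odds ratio was 16.5 (7.28 to 46.2) for chromosome 2 and 9.26 (3.58 to 28.2) for X. Exons of CG34205 overlap NtR on the other strand. Near-identical Hsp70 copies, and perhaps the transgene (not tested), share reads with Hsp70Bb, so both counts are uncertain.

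The largest increases at 0 h were FBgn0261404 (ratio 30.3, 95% counting interval 7.88 to 258), CG34205, CG14535 (4.03), CR43142 (3.29) and FBgn0058378 (3.19). After the shift tra led, with log2 fold changes of 5.13 (SE 0.205, adjusted p = 7.23e-07 by edgeR) at 12 h and 5.47 (SE 0.209, adjusted p = 4.38e-07) at 24 h. Also among the largest were Proc, which encodes the neuropeptide proctolin, with a ratio of 20.1 (6.62 to 99.9) at 12 h and 62 (10.8 to 2480) at 24 h, FBgn0058378 (3.27) at 12 h and CG30288 (21.2, 7 to 105) at 24 h. The largest decreases at 0 h were lncRNA:CR43263 (ratio 485, 166 to 2350), Cp7Fb (456, 81.6 to 18000), yip7, a digestive serine protease (264, 47.1 to 10500), Ir7c, an ionotropic receptor (164, 55.8 to 795) and CG17974 (124, 21.9 to 4910). At 12 h they were lncRNA:CR43822 (210, 37.3 to 8360), lncRNA:CR43263 (-7.04), Cp7Fb (-6.86), Ir7c (-6.39) and CG17974 (69.4, 18.8 to 579). At 24 h they were Cp7Fb (583, 104 to 23100), CG17974 (53.7, 17.9 to 264), lncRNA:CR43263 (-5.58), lncRNA:CR43822 (-5.49) and CG30371 (-4.80).

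**Figure D4:**
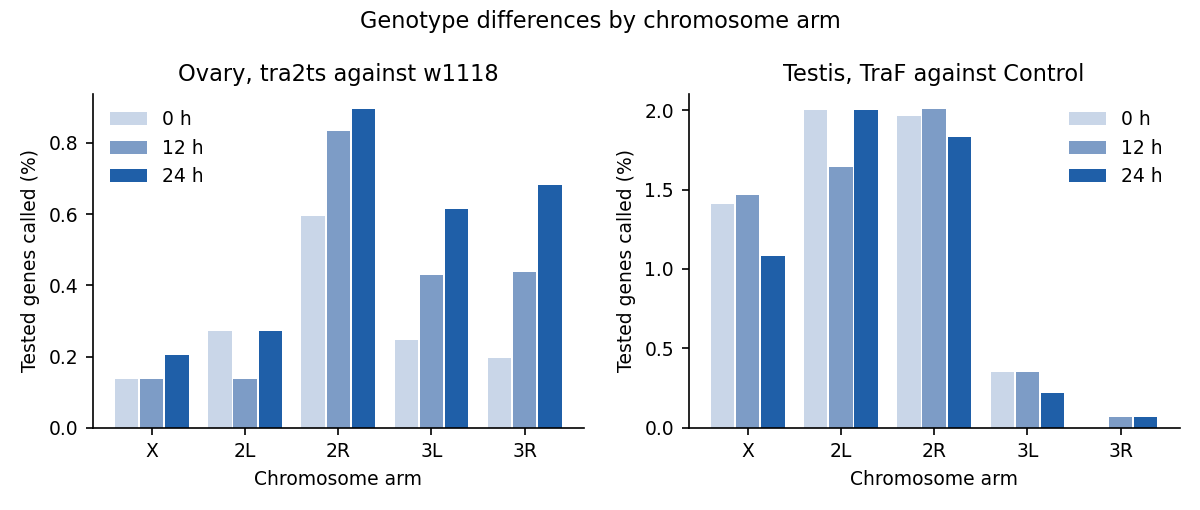
Percent of tested genes called in the genotype comparison, by chromosome arm, at 0, 12 and 24 h, for ovaries (left) and testes (right). In testes at 24 h, 107 of the 115 called genes with a known arm, chromosome 4 included, lay on X or chromosome 2. Chromosome 4 is not drawn.

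By group, gut genes lay lower in TraF testes at 0 h. Of 9 tested, 0 were above 0, the median was -2.07 and the camera adjusted p was 7.21e-11 (adjusted p = 0.0218 with an estimated correlation). Control 0 h replicate 1 stood apart, with a list median of 1.31 log2 CPM against -0.985 in its partner and -0.675 and -1.30 in TraF testes. Without it the median was -1.20 (adjusted p = 7.11e-10, adjusted p = 0.0719 with an estimated correlation), and the call with an estimated correlation was also lost without TraF 0 h replicate 1 (0.0856) and TraF 0 h replicate 2 (0.121). The amylase genes Amy-p (-2.89, SE 0.31) and Amy-d (0.657 ± 0.503 against 5.53 ± 3.55 CPM, adjusted p = 0.049 by edgeR) were lower in TraF testes, and 5 members were lower when adjusted over the list alone. The medians were -0.44 at 12 h and -0.77 at 24 h, with camera adjusted p of 0.0119 and 0.000636 (adjusted p = 0.837 and 0.228 with an estimated correlation). At 12 h the adjusted p was 0.489 without Control 12 h replicate 2 and 0.429 without TraF 12 h replicate 2, and without the Control library with accessory gland transcripts the median was -0.69. Amy-p alone was lower than in Control testes at those times (-1.91 and -1.60), and 2 members were lower at each when adjusted over the list alone. Amy-p and Amy-d are near-identical copies, so each count is uncertain.

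At 0 h the female soma list (19 tested) had a median of 0.34 (camera adjusted p = 0.00356, adjusted p = 0.788 with an estimated correlation). The testis soma list (22 tested) had a median of 0.25 (camera adjusted p = 0.00628, adjusted p = 0.788 with an estimated correlation). Without Control 0 h replicate 1 the adjusted p of these lists were 0.0618 and 0.0566. Fas3, an adhesion gene of the hub and of follicle cells, was the 1 member called in either (1.03, SE 0.185, adjusted p = 0.0247 by edgeR), over all genes and adjusted over the list alone. The hemocyte list (11 tested) had a median of 0.56 (camera adjusted p = 0.0116, adjusted p = 0.788 with an estimated correlation), with 0 called by edgeR over all genes and 1 higher adjusted over the list alone. No call remained without TraF 0 h replicate 2 (adjusted p = 0.227) or Control 0 h replicate 2 (0.0812). The proteasome list (45 tested) had a median of -0.12 (camera adjusted p = 0.04, adjusted p = 0.925 with an estimated correlation), with 0 called by edgeR either way. The call was lost without TraF 0 h replicate 2 (adjusted p = 0.105) and Control 0 h replicate 1 (0.312). At 12 h the spermatid list (49 tested, 0 called by edgeR) had a median of 0.17 (camera adjusted p = 0.00565, adjusted p = 0.97 with an estimated correlation). The adjusted p was 0.132 without Control 12 h replicate 1, the library with accessory gland transcripts, and 0.163 without Control 12 h replicate 2. The circadian list (15 tested) had a median of -0.26 (camera adjusted p = 0.0242, adjusted p = 0.837 with an estimated correlation), with 1 member lower adjusted over the list alone and 0 over all genes. It did not pass without TraF 12 h replicate 1 (adjusted p = 0.0953), TraF 12 h replicate 2 (0.0501) or Control 12 h replicate 2 (0.64). The accessory gland list (15 tested) had a median of -8.71 (camera adjusted p = 0.00125, adjusted p = 0.97 with an estimated correlation), with 11 lower adjusted over the list alone and 0 over all genes, and without Control 12 h replicate 1 its median was 1.02 and its adjusted p 0.452.

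In TraF against Control testes at 24 h, the antimicrobial list (19 tested) had a median of -0.47 (camera adjusted p = 0.00803, adjusted p = 0.921 with an estimated correlation, and adjusted p = 0.196 without Control 24 h replicate 2), and AttC, an attacin, was lower in TraF testes (-1.74, SE 0.321) over all genes and adjusted over the list alone. The muscle list (20 tested, 0 called by edgeR) had a median of -0.31 (camera adjusted p = 0.0302, adjusted p = 0.985 with an estimated correlation). This list lost its call without TraF 24 h replicate 1 (adjusted p = 0.837) and Control 24 h replicate 2 (0.447). The sex determination list had a median of -0.02 and a mean of 0.34 at 24 h (camera adjusted p = 0.000636, adjusted p = 0.228 with an estimated correlation), and tra was its 1 called member over all genes and adjusted over the list alone.

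Here too single libraries moved the counts. Without TraF replicate 1, TraF replicate 2, Control replicate 1 or Control replicate 2 of the time in question, edgeR called 24, 29, 52 and 36 genes at 0 h, 25, 19, 101 and 558 at 12 h, and 22, 18, 71 and 35 at 24 h.

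In control ovaries, a few single genes changed after the shift, led by Ace. Ace, which encodes acetylcholinesterase, went from 0.172 ± 0.0472 CPM at 0 h to 20.7 ± 6.83 CPM at 12 h and 10.8 ± 4.71 CPM at 24 h in w1118 ovaries. Its log2 fold changes were 6.85 (adjusted p = 0.00771 by edgeR) and 5.92. The other genes that rose at 12 h were CG7381 (3.13), NLaz, a lipocalin gene (2.24), and CG5390 (1.64), and those that fell were CG10581 (-5.37), CG10650 (-3.79) and rtet (-1.75). At 24 h, 9 genes rose, led by Ace, CG7381 (3.73), LManI (2.97), CG14079 (2.83) and NLaz (2.61), and 15 fell, led by Vajk3 (ratio 105, 95% counting interval 18.4 to 4170), CG10581 (-4.78), CG15247 (-4.67), dao (-3.90) and CG10650 (-3.88). Exons of CG10581 overlap Polr3E on the other strand. In tra2ts ovaries, a comparison chosen after the data were seen, edgeR called 1 gene higher and 1 lower at 12 h, and 17 higher and 12 lower at 24 h. Those at 24 h included Ace (3.94), CG7381 (3.51), CG10581 (-4.20) and narya (-3.60), and 16 genes were called in the same direction in both genotypes at 24 h. Single libraries moved these tra2ts counts: 0 genes were called at 12 h without any 1 of its 4 libraries, and at 24 h 0 without tra2ts 0 h replicate 1, 0 without 0 h replicate 2, 37 without 24 h replicate 1 and 10 without 24 h replicate 2, against 175 and 202 by DESeq2.

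Heat shock genes (18 tested) had medians of 0.70 at 12 h and 0.59 at 24 h in w1118 ovaries, with camera adjusted p of 8.67e-06 and 0.015 (adjusted p = 0.372 and 0.81 with an estimated correlation). edgeR called 0 over all genes and 1 at each time when adjusted over the list alone; the small heat shock gene Hsp23 was at 2.65 (SE 0.424) and 2.24 (SE 0.42). The list's level in replicates 1 and 2 was 4.64 and 4.98 log2 CPM at 0 h, 5.81 and 4.49 at 12 h, and 5.13 and 4.14 at 24 h. At 12 h the list passed without each library, with medians of 0.37 to 0.78, and at 24 h the adjusted p was 0.276 without w1118 24 h replicate 1 (median 0.05) and 0.305 without w1118 0 h replicate 2. Eggshell genes (27 tested) had medians of 0.48 and 1.05, with camera adjusted p of 3.83e-05 and 0.000242 (adjusted p = 0.372 and 0.699 with an estimated correlation). edgeR called 0 over all genes, and 0 and 4 adjusted over the list alone, with Cp38 at 2.36 (SE 0.529) at 24 h. The eggshell medians without each library were 0.44 to 0.68 at 12 h and 0.58 to 1.61 at 24 h, and without w1118 0 h replicate 1 the adjusted p with an estimated correlation were 0.00831 and 0.00908. Muscle genes (19 tested) had medians of -1.03 and -1.16, with camera adjusted p of 1.34e-06 and 1.47e-07 (adjusted p = 0.372 and 0.699 with an estimated correlation), and 0 and 7 were lower when adjusted over the list alone, with 0 over all genes by edgeR.

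Antimicrobial genes (21 tested, 0 called by edgeR) had medians of -2.23 and -2.68 in w1118 ovaries at 12 h and 24 h against 0 h, with camera adjusted p of 0.00463 and 0.00653 (adjusted p = 0.912 and 0.81 with an estimated correlation). The 0 h libraries differed, with a list level of -2.29 log2 CPM in replicate 1 and 1.47 in replicate 2, against -2.30 to -0.32 in the later w1118 libraries. Without 0 h replicate 2 the medians were 2.21 (adjusted p = 0.028) and 1.92 (adjusted p = 0.128), and without w1118 12 h replicate 2 the adjusted p at 12 h was 0.322. Ribosomal protein genes (82 tested, 0 called by edgeR) had medians of -0.35 and -0.26, with camera adjusted p of 3.83e-05 and 0.015 (adjusted p = 0.912 and 0.81 with an estimated correlation). Their adjusted p was 0.872 without w1118 0 h replicate 2 and 0.737 without w1118 12 h replicate 1 at 12 h, and 0.509 without w1118 0 h replicate 2 and 0.458 without w1118 24 h replicate 2 at 24 h. The meiotic arrest list (12 tested) had medians of 0.34 and 0.38, with camera adjusted p of 0.00463 and 0.034 (adjusted p = 0.372 and 0.81 with an estimated correlation), and its member mia, at 1.95 (SE 0.388) and 2.35 (SE 0.391), passed adjusted over the list alone and not over all genes. Its adjusted p was 0.0925 at 12 h without w1118 12 h replicate 1, and at 24 h it was 0.0503 without w1118 0 h replicate 1, 0.128 without w1118 0 h replicate 2 and 0.104 without w1118 24 h replicate 2.

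Further groups passed at 1 time in w1118 ovaries. At 12 h the DSX target list (8 tested) had a median of 0.39 (camera adjusted p = 0.0257, adjusted p = 0.372 with an estimated correlation), and Yp1, at 1.18 (SE 0.326), passed adjusted over the list alone and not over all genes. The list's adjusted p was 0.203 without w1118 12 h replicate 2 and 0.0766 without w1118 0 h replicate 1. The detoxification list (64 tested) had a median of -0.25 (camera adjusted p = 0.0335, adjusted p = 0.912 with an estimated correlation), with 2 higher and 2 lower adjusted over the list alone and 0 over all genes by edgeR. No call remained without w1118 12 h replicate 2 (adjusted p = 0.128) or w1118 0 h replicate 2 (0.266). At 24 h the testis soma list (21 tested) had a median of -0.27 (camera adjusted p = 0.015, adjusted p = 0.81 with an estimated correlation), with 2 lower adjusted over the list alone and 0 over all genes by edgeR. The call was lost without w1118 0 h replicate 2 (adjusted p = 0.186) and w1118 24 h replicate 1 (0.255). The gut list (5 tested) had a median of 2.07 (camera adjusted p = 0.0256, adjusted p = 0.81 with an estimated correlation), with 2 higher adjusted over the list alone and 0 over all genes by edgeR, and its member Jon25Biii, a digestive protease, stood at 3.66 ± 5.06 CPM at 24 h. The gut list's adjusted p was 0.998 without w1118 24 h replicate 1 and 0.201 without w1118 0 h replicate 1. Without the 2 ovary 24 h libraries with the most reads outside genes the 24 h adjusted p were 0.432 (heat shock), 0.401 (testis soma), 0.0774 (meiotic arrest) and 0.0705 (antimicrobial), fewer than 5 gut genes were tested, and the eggshell and ribosomal protein medians were 0.56 and -0.41. At 12 h the detoxification adjusted p was 0.0541. Without w1118 0 h replicate 1, 0 h replicate 2, or replicate 1 or 2 of the later time, edgeR called 9, 0, 0 and 1 genes at 12 h and 18, 0, 5 and 14 at 24 h, against 803 and 1002 at an unadjusted p under 0.05 and 166 and 290 by DESeq2.

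In Control testes, 25 genes rose and 12 fell at 12 h, and 209 rose and 116 fell at 24 h. CG6409 went from 58.4 ± 0.0339 CPM at 0 h to 504 ± 133 CPM at 12 h (3.11, adjusted p = 0.000233 by edgeR). Others that rose at 12 h were CG16995 (3.43), Pxd, a peroxidase gene (3.00), Ugt37C1 (2.73) and the cuticle protein gene Cpr100A (2.72), and those that fell included CG14563 (ratio 22.4, 95% counting interval 7.41 to 111), CG31087 (-3.51), CG12116 (-1.69), CG34027 (-1.37) and Gs1, a glutamine synthetase gene (-1.22). At 24 h the largest increases were Cyp4g1, a hydrocarbon-forming P450 of oenocytes, from 2.96 ± 0.185 to 232 ± 160 CPM (6.29), fiz (5.15), the eye pigment transporter gene st (4.90), the cecropin gene CecC (4.29) and CG10514 (3.91). The largest decreases were yip7 (at least 100-fold), CG14563 (-4.02), CG17283 (-3.49), SmydA-6 (-2.54) and Zip42C.1 (-2.49). The targeted gene tra also fell (-0.80, adjusted p = 0.0489 by edgeR). In TraF testes, a comparison chosen after the data were seen, 40 genes rose and 42 fell at 12 h, and 175 rose and 129 fell at 24 h, among them tra (3.42 and 3.61), CG6409 (3.08 at 12 h) and Amy-p (3.12 and 4.11). Without TraF 0 h replicate 1, 0 h replicate 2, or replicate 1 or 2 of the later time, edgeR called 4, 13, 7 and 11 genes in TraF testes at 12 h and 22, 36, 26 and 26 at 24 h. Of the 325 genes called in Control testes at 24 h, 319 had the same sign in TraF testes and 159 were called there in the same direction.

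By group, heat shock genes (17 tested) had a median of 0.39 in Control testes at 12 h (camera adjusted p = 0.000196, adjusted p = 0.668 with an estimated correlation), and without Control 12 h replicate 2 the median was -0.08 and the adjusted p 0.803. Hsp23 (1.46, SE 0.208) and Hsp67Bc (1.90, SE 0.273) rose, and 3 members rose when adjusted over the list alone. The circadian list (15 tested) had a median of 0.15 (camera adjusted p = 0.0224, adjusted p = 0.753 with an estimated correlation), with 3 higher adjusted over the list alone and 0 over all genes by edgeR. It did not pass without Control 12 h replicate 2 (adjusted p = 0.803), Control 0 h replicate 1 (0.059) or Control 0 h replicate 2 (0.0783). The accessory gland list (15 tested) had a median of 8.64 (camera adjusted p = 2.1e-06, adjusted p = 0.753 with an estimated correlation), with 12 higher adjusted over the list alone and 0 over all genes, and without the Control library that held those transcripts its median was -1.32 and its adjusted p 0.987. The ribosomal protein list (87 tested, 0 called by edgeR) had a median of 0.18 (camera adjusted p = 0.0412, adjusted p = 0.937 with an estimated correlation), and without that library a median of -0.25 (adjusted p = 7.19e-06); its adjusted p was 0.983 without Control 0 h replicate 2. At 24 h the detoxification list (81 tested) had a median of 0.29 (camera adjusted p = 0.0356, adjusted p = 0.901 with an estimated correlation). This list lost its call without Control 0 h replicate 2 (adjusted p = 0.322), Control 24 h replicate 2 (0.0516) and Control 24 h replicate 1 (0.0635). In it 5 genes rose, among them Cyp6d2 (1.26, SE 0.198) and Cyp40 (0.84, SE 0.134), and 9 rose and 2 fell when adjusted over the list alone. Without Control 0 h replicate 1, 0 h replicate 2, or replicate 1 or 2 of the later time, edgeR called 1, 7, 13 and 458 genes at 12 h and 24, 68, 102 and 28 at 24 h.

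Control ovaries and control testes at 0 h differed in most genes, which served to place the sex-biased genes. edgeR called 3862 genes higher in ovaries and 6074 higher in testes of 12411 tested. The vitelline membrane gene Vm26Aa stood at 8050 ± 1010 CPM in ovaries and 0.146 CPM in testes (15.7), and the eggshell genes Cp19 (at least 14400-fold) and psd (at least 11400-fold) and the yolk protein gene Yp2 (ratio 87900, 95% counting interval 24300 to 726000) were also far higher in ovaries. In testes the sperm leucyl aminopeptidase gene S-Lap7 (at least 105000-fold), CG33340 (at least 81500-fold), CG2127 (at least 78700-fold), CG12860 (at least 78100-fold) and CG8701 (at least 70100-fold) were higher. Of the sex determination genes, Sxl was higher in ovaries (3.36), and fru (-3.24), tra2 (-0.87) and dsx (-0.79, adjusted p = 0.0498 by edgeR) were lower, while tra was not called (-0.36, adjusted p = 0.116). The genotypes of the tissues also differ here, and tissue cannot be told apart from genotype: w, the eye color gene that is mutant in w1118, was at -7.35.

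Of the 25 lists, 7 passed in no comparison planned before the data were seen: dosage compensation, female germline, JAK/STAT, ecdysone, fat body, reproductive tract and Y-linked genes, with lowest camera adjusted p of 0.242, 0.155, 0.338, 0.0561, 0.353, 0.354 and 0.533. In ovaries 0 Y-linked genes were tested, and accessory gland and reproductive tract had 4 tested members each, too few for a test. The transgene marker list had 3 tested members in ovaries and 4 in testes and was not tested; its members include w, which stood between 44.9 and 73.3 CPM in testis groups and between 0.275 and 1.96 CPM in ovary groups. The highest ovary value came from tra2ts 12 h replicate 2, at 3.66 CPM against 0.269 in its partner and at most 0.778 in the other ovary libraries.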

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

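The tests of arms and of signs at 0 h were set before their results were seen; those of the libraries that stood apart, the odds against chromosome 3 alone, and the repeats of the gene lists without single libraries or genes, were chosen after.

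A test of the difference between the genotypes' changes singled out tra in testes, with log2 fold changes of 4.07 at 12 h and 4.41 at 24 h; its adjusted p over 14 alternatives at each time, DESeq2 among them, was at most 0.00601 and 0.00332. The same kind of test singled out the DSX target list in ovaries at 12 h, with a median of -0.754. With a replicate block and an estimated correlation, that list's camera adjusted p was 0.0857 and it was not called. Its adjusted p with an estimated correlation was 0.0395, and leaving out each of the 8 libraries in turn ended that call, with medians between -0.605 (without tra2ts 12 h replicate 1, adjusted p = 0.213) and -0.87 (without tra2ts 12 h replicate 2, adjusted p = 0.0543), as did leaving out Fad2 (adjusted p = 0.454). The 0 h libraries enter the difference: at 12 h tra2ts against w1118 ovaries had log2 fold changes of 0.0723 for Yp1 and 0.299 for Yp2, whereas Yp1 (1.12, SE 0.326) and Yp2 (1.34, SE 0.35) in tra2ts against w1118 ovaries at 0 h had adjusted p by edgeR of 0.404 and 0.275 over all genes, and of 0.0261 each adjusted over the list alone.

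Genotype differences after the shift were largely there at 0 h, in libraries that share nothing with those of 24 h. In ovaries 97.9% (95% exact interval 88.7 to 99.9) of the genes called at 24 h had the same sign at 0 h, and in testes, without tra, 97.5% (92.9 to 99.5), against 59.9% and 64.8% of all genes, which argues against a start only after the shift for these sets. For testes, the odds ratio of 11 (5.4 to 26.2) for lying on X or chromosome 2, and 16.5 (7.28 to 46.2) for chromosome 2 and 9.26 (3.58 to 28.2) for X when each is set against chromosome 3 alone without tra, is consistent with background differences of the transgenic stock on these chromosomes, where the labels' genotypes differ. For ovaries, the odds ratio for chromosome 2, where tra2 lies, was 1.17 (0.614 to 2.19) from 46 genes with a known arm, after 2.33 (0.962 to 5.87) at 0 h and 1.48 (0.705 to 3.08) at 12 h, so stock background there and other sources cannot be told apart. These odds pool 2L with 2R, the arm of tra2. On 2R 0.6%, 0.83% and 0.89% of tested genes were called at 0, 12 and 24 h. The shares were 0.27%, 0.14% and 0.27% on 2L, 0.25%, 0.43% and 0.61% on 3L, and 0.19%, 0.44% and 0.68% on 3R. The odds for 2R alone were not tested. An effect of the transgenes or alleles already at 18 °C stays open and was not tested; tra itself was higher in TraF testes at 0 h (1.07).

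A library of each genotype at 24 h stood apart in ovaries, w1118 24 h replicate 1 and tra2ts 24 h replicate 2, with 2.48% and 2.47% of reads outside genes. Time at the restrictive temperature is argued against as the whole source, since another library of 24 h had 1.1%, below the median of 1.28% at 0 and 12 h. Across genes, the difference from the partner library fell with exonic length, with rho of -0.437 and -0.733, which is consistent with shorter RNA. In the other 4 groups rho, replicate 1 minus replicate 2, was 0.229 to 0.394, so length trends were not confined to these 2 libraries. The gut list stood at medians of 0.855 and -0.597 log2 CPM against at most -0.781 elsewhere in ovaries, and the fat body list at 1.33 and 2.10 against at most 1.23. Both lists were highest in these 2 libraries, as tissue carried over at dissection predicts. Of their genes, 5 of 28 and 11 of 16 passed the ovary filter, Jon25Biii and Lsp2 among them. Genes could pass that filter through these 2 libraries, and without them fewer than 5 gut genes were tested. The gut values therefore cannot decide on carry-over. In tra2ts 24 h replicate 2 the spermatid list was at 2.97 log2 CPM against at most 1.42 in the other ovary libraries, and lists at their lowest among ovary libraries included female soma (2.71), testis soma (2.81), JAK/STAT (4.70) and circadian (4.42). Second lowest for female soma (3.15) and JAK/STAT (4.88) was w1118 24 h replicate 1. Whether length, carry-over or a biological cause bears on these lists was not tested.

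In Control testes at 12 h, replicate 1 held more of most accessory gland transcripts than its partner, with a median log2 difference of 9.87 over 15 genes. Acp36DE stood at 1320 against 8.9 CPM and Mst57Da at 714 against 0.0947 CPM. The medians of the fat body, muscle, hemocyte, reproductive tract and gut lists differed by -0.434 to 0.0552, which is consistent with accessory gland carried over at dissection rather than a mix of tissues. Of the 15 genes, EbpIII (218 against 174 CPM), Est-6 (15.8 against 5.35), Spn28Dc (5.33 against 4.69), Gld (4.04 against 5.16) and EbpII (0.0952 against 0.0473) did not share the large difference, and no biological explanation was tested.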

How the results depend on the processing

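The runs without libraries that stood apart, and the repeats of lists without single libraries or genes, were chosen after seeing the data. Counts below are called genes by edgeR unless stated; the cause of the changes was not tested.

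Genotype counts in ovaries at 0, 12 and 24 h were 24, 34 and 47; they were 52, 54 and 107 with no filter on low counts, 105, 111 and 217 by DESeq2, and 22, 18 and 0 with the compared groups alone. The time counts in w1118 ovaries, 7 and 24, were 15 and 109 with no filter, 166 and 290 by DESeq2, 14 and 43 with a replicate block, and 2 and 0 with the compared groups alone. Without the 2 ovary libraries of 24 h with the most reads outside genes, the 24 h genotype and time counts were both 12. The ovary switch counts of 0 were 1 by DESeq2 at 12 h and at 24 h, and 1 with no filter at 24 h, rtet each time, whose adjusted p ranged from 7.17e-11 to 1 over 15 alternatives at 24 h. Genotype counts in testes, 131, 127 and 121, were 216, 282 and 205 by DESeq2; at 0 h the compared groups alone gave 200, and at 12 h they gave 34 and the replicate block 195. The time counts in Control testes, 37 and 325, were 217 and 553 by DESeq2 and 95 and 579 with a replicate block, and 7 at 12 h with the compared groups alone. The tra2ts time counts, 2 and 29, were 11 and 66 with no filter, 175 and 202 by DESeq2, 1 and 40 with a replicate block, 207 and 0 with the compared groups alone, and 12 at 24 h without the 2 libraries. The TraF time counts, 82 and 304, were 261 and 637 by DESeq2, 163 and 628 with a replicate block, and 366 and 672 with the compared groups alone. The testis switch counts of 1 were 4 and 3 by DESeq2, and 2 at 24 h with a replicate block, which added Muc11A. The 77 list calls became 2 with an estimated correlation, which widens the variance where members move together. Leaving out each library of the compared groups in turn, 21 of the 77 passed in the same direction every time and 56 did not. With an estimated correlation, the DSX target list in the ovary switch at 12 h was lost without each of its 8 libraries in turn (adjusted p of 0.0539 to 0.213). Its adjusted p of 0.0395 was 0.0857 with a replicate block, which ended the call, 0.0455 with RLE scaling, and 0.054 to 0.454 without bond, Yp2, Yp1, bab2 or Fad2, each left out alone. The gut list in the testis genotype comparison at 0 h passed without Control 0 h replicate 2 alone (adjusted p = 0.0252). Lists that passed so without a library and not with all were eggshell in the ovary switch at 24 h (0.007), in w1118 time at 12 h (0.00831) and at 24 h (0.00908) without w1118 0 h replicate 1, eggshell (0.0139) and hemocyte (0.0173) in the ovary genotype comparison at 0 h without w1118 0 h replicate 2, and accessory gland in Control time at 12 h without Control 12 h replicate 2 (0.0498).

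Leaving out 1 library gave 1 to 4, 1 to 6 and 4 to 72 genes for the ovary genotype comparison at 0, 12 and 24 h, 0 to 9 and 0 to 18 for w1118 time, 0 at 12 h and 0 to 1 at 24 h for the ovary switch, 24 to 52, 19 to 558 and 18 to 71 for the testis genotype comparison, 1 to 458 and 24 to 102 for Control time, 0 at 12 h and 0 to 37 at 24 h for tra2ts time, 4 to 13 and 22 to 36 for TraF time, and 1 to 96 at 12 h and 1 at 24 h for the testis switch. The highest values came without tra2ts 24 h replicate 1 (72) and without Control 12 h replicate 2 (558, 458 and 96). Fewer libraries leave fewer degrees of freedom.

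RLE scaling and the robust prior kept every count within 1.5 times, as did all alternatives for ovary against testis (9258 to 10186 genes against 9936). No named gene's call reversed in direction: of its values under the alternatives, 1265 stayed on their side of the threshold, 433 fell short of it and 7 passed it anew. As to pairing, deviations from the group mean of same-numbered libraries correlated above 0.1, across genes, for 12 of 15 pairs of groups in ovaries (-0.49 to 0.43) and 11 of 15 in testes (-0.00066 to 0.39). In testes 0 pairs lay below -0.1. Testis libraries numbered 1 had 2.24% to 2.46% of reads outside genes, and those numbered 2 had 2% to 2.23%. The labels name no shared day, and the main fits did not pair the libraries. A batch shared by same-numbered libraries stays open in both tissues, and the main counts leave it out. In ovaries, replicate 2 leaned to short genes relative to its partner in each group except w1118 at 24 h. Depth limits genes at a few counts, where folds are bounds.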

Other observations

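The genes in this part, and the time courses of tra2ts and TraF, were chosen after the data were seen. The comparison of TraF with Control, the testis switch and the time courses of Control and w1118 were planned.

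Fad2, low in tra2ts ovaries after the shift, was present in TraF testes at 0 h, at 4.13 ± 0.473 CPM. It was absent from Control testes, with 160 counts against 0 (at least 75.1-fold). TraF testes held 70 and 2 counts at 12 h, and 3 and 11 counts at 24 h. The genotype difference at 0 h did not pass by edgeR (adjusted p = 0.0678), nor did the testis switch at 12 h or 24 h (adjusted p = 1).

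mia, which encodes a testis-specific TFIID subunit homolog, rose in TraF testes at 24 h against 0 h, with a log2 fold change of 1.10 (SE 0.126, adjusted p = 0.0028 by edgeR), and it passed without each library in turn (adjusted p of at most 0.0379). In Control testes at 24 h it was 0.846 (adjusted p = 0.00949), and 0.0888 without 0 h replicate 1, 0.0775 without 0 h replicate 2 and 0.0837 without 24 h replicate 2. In tra2ts ovaries at 24 h it was 2.44 (adjusted p = 0.0457), and the call was lost without each library in turn (0.0563 to 0.492) and with the compared groups alone (0.497). In w1118 ovaries it did not pass by edgeR over all genes, with adjusted p of 0.158 at 12 h and 0.0507 at 24 h. It stood at 1.33 ± 0.203, 5.16 ± 0.782 and 6.80 ± 2.26 CPM in w1118 ovaries at 0, 12 and 24 h, at 0.936 ± 0.34, 3.25 ± 0.299 and 5.15 ± 0.726 CPM in tra2ts ovaries, and at 24.3 ± 1.54, 34.9 ± 0.446 and 43.7 ± 0.691 CPM in Control testes.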
